A study of Mus musculus with 15 samples.

How the data were processed

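The data were log2 intensities of 28853 array probe sets in 15 arrays, 1 array per sample, from cultured mouse cardiac colony-forming unit fibroblasts. Per the labels the samples were total RNA labelled for Affymetrix whole-transcript arrays. The deposited values are on a log2 scale, as the authors made them, and the submitters' processing notes name RMA and limma with no version or role. Array medians lay between 5.59 and 5.72, as in values normalized between arrays. Between 33 and 63 genes in a group had exactly equal values in its 3 arrays, Mki67 in untreated small colonies among them. Pairs of arrays shared 171 to 305 equal values within groups and 126 to 308 between groups, as the median polish of RMA can give, and the variance in the tests was pooled over all 15 arrays. Background correction settings were not stated, and raw scans were not used here. For arrays, precision is limited by their number, 3 in each of 5 groups. The labels mention an inhibitor of PDGF receptors in the treatment protocol, but no sample was labelled with it, so no such comparison was made.

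Of the 28853 probe sets 23410 were listed with a gene, 21789 of them with 1 symbol and 1621 with several, and 5443 were not listed. Probe sets that named 1 gene were kept, and where 999 genes had several, the probe set with the highest mean over all arrays was used. This left 19938 genes, 69.1% of the array. Of the kept probe sets 21698 were matched by gene identifier to the GRCm38.p6 RefSeq table and 91 were not. Ly6a, which encodes SCA1, was named by no probe set and Cdkn1a only together with another gene, so neither was analysed here.

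Groups were taken from the labels. Linear models were fitted with limma 3.58.1 in R 4.3.3 over all 15 arrays (10 residual degrees of freedom, prior degrees of freedom 5.80), with moderated tests and Benjamini-Hochberg adjustment in each comparison over 19938 genes, 2-sided, at a threshold of 0.05. The median SE of a change between groups was 0.0778. The 7 comparisons were passage in large colonies, large against small untreated colonies at passage 5, PDGF-AB in small colonies at passage 5, passage in treated small colonies, treated small against untreated large colonies at each passage, and the difference between the passage changes. Comparisons, alternatives, gene lists and the rule for named genes were fixed before the data were examined. Named genes were the 8 largest rises and the 8 largest falls among called genes whose 3 arrays in 1 group all lay beyond those of the other group (a condition not applied to the difference), up to 4 members of each list with the smallest adjusted p, and 7 fixed genes (Pdgfra, Pdgfrb, Ly6a, Pecam1, Mki67, Cdkn1a and Cdkn2a). Predicted genes, microRNAs and other unnamed transcripts were left out of the largest changes.

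The 37 lists held 570 genes, of which 529 were tested, 10 were on probe sets naming several genes and 31 on none. They covered the cell cycle, matrix, signalling, metabolism and stress responses, developmental transcription factors, stromal states and markers of other cell types. Lists were tested with camera at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, which tests whether the genes of a list move 1 way on balance and does not compare them with other genes. Counts were also adjusted over the list alone.

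The alternatives were centring arrays on their medians, cyclic loess between arrays, leaving out genes below the median level, all probe sets, the mean over the probe sets of a gene, the compared arrays alone, trend and robust variance moderation, array weights, a replicate block, a minimum of 2-fold, and leaving out each array in turn. Replicate numbers did not meet the rule set for pairing in any comparison of a pair of groups. For passage in large colonies the correlations between arrays of the same number, after subtraction of the group means, were 0.208, 0.0984 and 0.202. There 6 of 6 arrays matched best with their own number, against 0 to 4 of 6 in the other comparisons. Pairing of the large colonies thus stays open. The pipeline was tested on simulated data, with changes added between treated and untreated small colonies at passage 5. Of the added changes 20% of those of 0.25 and 92% of those of 0.5 were called, and 1 moved list was recovered. Only 50 genes were changed at each size among 19938, far fewer than were called in the data. The adjusted threshold was therefore stricter than in the data, and these shares are not the sensitivity of the real comparisons. The list genes were drawn at random with independent noise, so the recovery says nothing of lists whose genes vary together. Chromosome shifts were taken over 9955 genes at or above the median level on the autosomes and X, as the median change of the genes of a chromosome minus the median of all of these.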

Results

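RNA from cultured mouse cardiac colony-forming unit fibroblasts (cCFU-F) was measured on 15 Affymetrix mouse gene arrays, 3 in each of 5 groups. cCFU-F are stromal cells of the heart that form colonies when plated at low density, and the labels describe the sorted cells as SCA1 positive, PDGFRα positive and CD31 negative. The groups were untreated large colonies at passage 5 and at passage 15, untreated small colonies at passage 5, and small colonies grown with 50 ng/ml PDGF-AB (a platelet-derived growth factor that binds PDGFRα and PDGFRβ) at passage 5 and at passage 15. No untreated small colonies at passage 15 were among the groups, so colony size and PDGF-AB were confounded at passage 15 and wherever treated small colonies were set against large ones. Values are log2 intensities. Levels are given with the SD over 3 arrays (n = 3), changes as log2 differences with the SE of the fit, and adjusted p-values are from limma over 19938 genes.

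Array medians lay between 5.59 and 5.72. Pearson's r across genes was 0.997 to 0.998 between arrays of the same group and 0.958 to 0.991 between arrays of different groups, where genes are not independent replicates. The labels did not say whether the 3 arrays of a group came from separate cultures or animals, so the p-values measure the spread between these arrays, which may be technical. The first 2 principal components held 38.2% and 34.5% of the variance. Xist, the RNA that coats the inactive X chromosome of female cells, lay between 8.93 and 10.88 in the 15 arrays, and the 5 measured Y-linked genes lay between 2.24 and 3.42, in cells labelled male. The median over all genes and arrays was 6.00. The lower quartile of the probe sets lay between 4.06 and 4.23, and folds, which are ratios of intensities, depend on background where a level was near or below it. Xist was chosen after its values were seen.

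**Figure D1:**
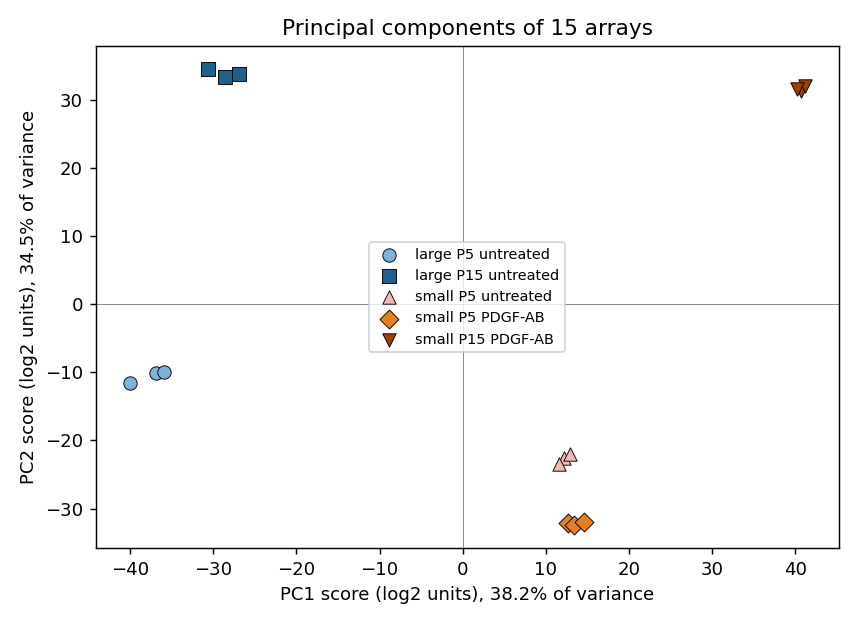
Principal component 1 (horizontal axis, 38.2% of the variance) and component 2 (vertical axis, 34.5%) of the 19938 genes, with 1 point for each of the 15 arrays, coloured by group. The 3 arrays of each group lie together, with large colonies at negative values and small colonies at positive values of component 1.

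The comparison of passage 15 with passage 5 in untreated large colonies asked what changed with time in culture. Cell division genes rose together. Ccna2 (cyclin A2, needed for S phase and entry into mitosis) went from 5.39 ± 0.10 to 9.61 ± 0.078, a rise of 18.7-fold. Mki67, the proliferation antigen, went from 5.41 ± 0.036 to 8.18 ± 0.16, a 6.83-fold rise. Pdgfra, the receptor used to sort the cells, rose 4.8-fold from 6.58 ± 0.12 to 8.84 ± 0.15 (adjusted p = 1.7e-12), and Cd34, a surface protein of stromal and vascular progenitors, rose 10.8-fold. The largest falls were in Serpinb6c (a protease inhibitor, 20.9-fold) and Cdo1 (cysteine dioxygenase, 18-fold).

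All 19 measured mitosis genes rose, with a median change of 2.54 (adjusted p = 6.4e-29), among them the spindle genes Nusap1 (3.13), Plk1 (3.53) and Kif11 (3.55). All 20 DNA replication genes rose too (median 1.96, adjusted p = 1.2e-25), including Chaf1b (3.03), Mcm6 (2.75) and Ccne2 (3.09). The largest rises also included the kinase Bub1 (3.89 ± 0.099), the topoisomerase Top2a (3.66 ± 0.091), the histone H2bc3 (4.01 ± 0.12), the replication clamp partner Pclaf (3.79 ± 0.077), Fam111a (4.22) and Tcf19 (3.73). Pgm5, a protein of muscle cell adhesions, rose by 4.06 ± 0.076. Of 14 p53 targets 11 fell, such as Trp53inp1 (-0.99), Phlda3 (-0.58) and Ccng1 (-0.46), while Sesn1 rose (0.62). The median of the p53 targets was -0.41 (adjusted p = 0.00221), with adjusted p = 0.19 under an estimated correlation. Cdkn2a, which encodes the cell cycle inhibitors p16 and p19ARF (not told apart here), fell by 0.44 with an SE of 0.077.

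Matrix and secreted factors moved both ways in the same comparison. Fibrillar matrix genes rose in 10 and fell in 7 of 19 cases (median 0.31, adjusted p = 0.00873), with rises in the collagens Col6a3 (1.90) and Col1a1 (1.43) and in the matricellular gene Postn (1.36). Secreted factors linked to senescence rose in 9 of 17 cases (median 0.30, adjusted p = 0.0226), including the stromelysin Mmp3 (3.12), the growth factor Hgf (2.87) and the IGF carrier Igfbp4 (2.86). The matrix glycoprotein Efemp1 (-3.54), the guidance factor Sema3d (-3.02) and the Notch target Hey2 (-2.70) fell. Other large falls were in Smpdl3a (-3.44), Lmcd1 (-3.10) and Tnfsf18 (-3.01). The ligand gene Pdgfd (-2.07), the pericyte marker Rgs5 (-1.69) and the stress genes Chac1 (-1.68) and Ddit3 (-1.75) also fell. With an estimated correlation fibrillar matrix had adjusted p = 0.299 and the senescence list adjusted p = 0.299, and when genes below the median level were left out these lists had adjusted p = 0.0709 and adjusted p = 0.116.

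limma called 7196 of 19938 genes changed between passages in large colonies, 3477 higher and 3719 lower at passage 15. Of these 751 changed at least 2-fold, 516 higher and 235 lower. In the set test camera 9 of 37 lists were called, and mitosis and DNA replication held with an estimated correlation (adjusted p = 0.0075 and adjusted p = 4.7e-04). Over the 541 memberships of genes in lists, 316 were called over all genes and 329 when adjusted over the list alone.

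**Figure D2:**
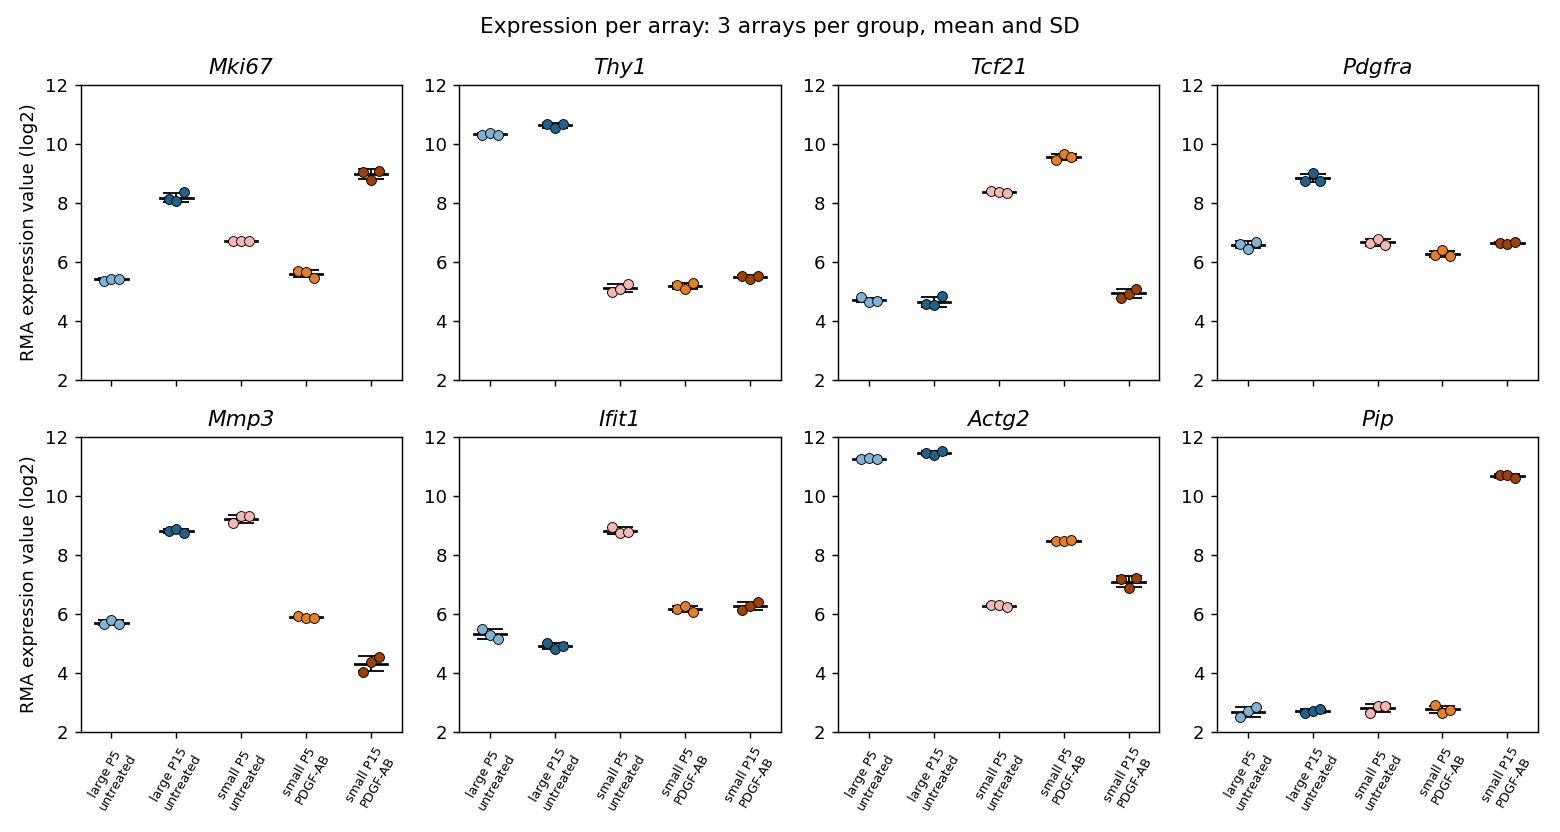
Log2 level (vertical axis) of 8 genes in the 5 groups (horizontal axis), where points are the 3 arrays of a group, bars their mean and whiskers their SD. Mki67 was lowest in large colonies at passage 5 and highest in treated small colonies at passage 15, Thy1 was high only in the large groups of these 5, and Pip was high only in treated small colonies at passage 15.

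Large and small colonies were compared untreated at passage 5, as large minus small, to find what sets them apart. The groups differed most in single genes with intensity ratios of over 100. Efemp1 (fibulin 3) stood at 11.36 ± 0.064 in large and 4.19 ± 0.12 in small colonies, 144-fold higher in large ones (adjusted p = 6.8e-20). In small colonies it lay within the range of the lower quartiles of the arrays (4.06 to 4.23), so this fold depends on background. The secreted peroxidase Gpx3 was 113-fold higher and the growth factor Fgf7 87.1-fold higher in large colonies. The fibroblast surface protein Thy1 stood at 10.33 ± 0.050 in large and 5.11 ± 0.13 in small colonies. On the other side the xylosyltransferase gene Gxylt2 was 56.3-fold lower in large colonies, and the cardiac transcription factor Tbx20 stood at 3.30 ± 0.23 in large and 8.61 ± 0.065 in small ones. The level of Tbx20 in large colonies lay within the range of the Y-linked genes, so no fold is given. Pdgfra (6.58 ± 0.12 in large, 6.66 ± 0.11 in small, adjusted p = 0.491), Pdgfrb (adjusted p = 0.451) and the endothelial gene Pecam1, which encodes CD31 (adjusted p = 0.182), did not pass the test.

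Cardiac and lateral mesoderm transcription factors split between the colony types, with 5 higher and 8 lower in large colonies of 20. Tbx5 was higher in large colonies (4.47 ± 0.086), and Tbx20, the epicardial factor Tcf21 (-3.67 ± 0.089) and Gata4 (-2.62 ± 0.099) were lower. As a list they did not pass (median -0.032, adjusted p = 0.111). Hox genes, which mark position along the body axis, were higher in 14 and lower in 2 of 37 cases (median 0.14, adjusted p = 0.00512), including Hoxb9 (3.30), Hoxb5 (1.80) and Hoxa5 (1.46), and this call had adjusted p = 0.0868 with an estimated correlation. Interferon response genes were lower in large colonies in 15 of 18 cases (median -1.24, adjusted p = 1.5e-14), such as Ifit1 (-3.52), Oasl2 (-2.74) and Stat2 (-1.73). All 19 mitosis genes were lower (median -1.08, adjusted p = 6.5e-16), Mki67 among them (-1.30 ± 0.089), and all 15 cholesterol synthesis genes were lower (median -0.64, adjusted p = 6.5e-10), such as Fdft1 (-1.12) and Sc5d (-1.07).

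Matrix genes were lower in large colonies in 11 and higher in 3 of 19 cases (median -0.72, adjusted p = 2.5e-05), including Postn (-3.63), Col3a1 (-2.55) and the crosslinking enzyme gene Loxl1 (-2.34), and with adjusted p = 0.0995 under an estimated correlation. Contractile and myofibroblast genes were higher in 12 of 16 cases (median 0.36, adjusted p = 8.8e-06), including the smooth muscle actin Actg2 (4.99). Other genes far higher in large colonies were the retinoic acid enzyme gene Aldh1a3 (5.89), the prostaglandin transporter Slco2a1 (5.22), Glipr1 (5.85), Tnfsf15 (5.26) and Igfbp3 (4.09). Other genes far lower were the TGF-beta coreceptor Eng (-4.01), Rerg (-4.56), Itgbl1 (-4.37), Nrep (-4.07), Srpx2 (-3.95) and Wfdc17 (-3.83). The pericyte marker Rgs5 was higher (2.92) and the monocyte gene Cd14 lower (-1.86) in large colonies, while neither the pericyte list (adjusted p = 0.779) nor the leukocyte list (adjusted p = 0.659) passed.

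limma called 7216 genes different between large and small colonies at passage 5, 3627 higher and 3589 lower in large ones. Of these 783 differed by at least 2-fold, 362 higher and 421 lower. Of 13 lists called by camera, mitosis, interferon response, cholesterol synthesis and contractile genes held with an estimated correlation (adjusted p = 0.0373, adjusted p = 0.00141, adjusted p = 0.0373 and adjusted p = 0.0204). Over the 541 list memberships 332 were called over all genes and 346 when adjusted over the list alone. Among the 9955 genes at or above the median level, placed by the GRCm38.p6 RefSeq gene table, the median change relative to all of them was -0.320 on chromosome 15 and 0.237 on chromosome 13.

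Small colonies with and without PDGF-AB at passage 5 were compared to find the response to the growth factor. The largest falls included that of Aspn (asporin, a small matrix protein), which went from 7.20 ± 0.028 without to 3.41 ± 0.14 with PDGF-AB (adjusted p = 2.8e-14), a mean at the upper end of the range of the Y-linked genes, so no fold is given. Mmp13 fell 12.8-fold, Mmp3 10.2-fold and the proteoglycan Ogn 9.25-fold. Rises were smaller, including 5.5-fold in Clca3a1, a chloride channel accessory gene, 4.6-fold in Actg2 and 4.4-fold in the growth factor gene Igf2. Pdgfra fell from 6.66 ± 0.11 to 6.28 ± 0.10 (adjusted p = 0.00218). Pdgfrb fell by 0.19 (adjusted p = 0.0221), a call lost without untreated small replicate 1 (adjusted p = 0.0966) or 2 (0.0686), without treated replicate 2 (0.0617) or 3 (0.0800), and with the compared arrays alone (0.0525).

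Every one of the 19 mitosis genes fell with PDGF-AB (median -1.13, adjusted p = 1.4e-21), such as Nusap1 (-1.39), Ccna2 (-1.37) and Plk1 (-1.52), and Mki67 went from 6.71, equal in the 3 untreated arrays, to 5.60 ± 0.12. DNA replication genes fell in 17 of 20 cases (median -0.64, adjusted p = 8.8e-12), including the helicase subunits Mcm7 (-1.32), Mcm6 (-0.97) and Mcm4 (-0.70). Interferon response genes fell in 17 of 18 cases (median -1.19, adjusted p = 2.0e-19), including Usp18 (-2.73), Ifit1 (-2.65), Oasl2 (-2.61) and Ifit3 (-1.74). The 13 macrophage and leukocyte markers, of which 2 lay above the median level, had a median change of 0.00464, and the 2 that were called, Cd14 (-1.24) and Cd68 (-0.23), fell. The call of Cd68 (adjusted p = 0.0308) was lost without untreated small replicate 1 (adjusted p = 0.128) or 2 (0.0935), without treated replicate 3 (0.166) and with the compared arrays alone (0.0814). Cholesterol synthesis genes fell in 13 of 15 cases (median -0.55, adjusted p = 2.4e-10), for example Hmgcs1 (-0.73), Idi1 (-0.78) and Lss (-0.76). Contractile genes rose in 14 of 16 cases with no fall (median 0.40, adjusted p = 1.5e-13), among them the myosin light chain Myl9 (1.56), the tropomyosin Tpm2 (1.18) and the calponin Cnn1 (1.24).

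Immediate early genes, the first transcribed after a growth signal, rose in 13 and fell in 2 of 17 cases (median 0.31, adjusted p = 3.3e-07), including Egr2 (1.17), Zfp36 (1.11), Fos (0.95) and Egr1 (0.55). Fibrillar matrix genes fell in 11 of 19 cases (median -0.28, adjusted p = 6.0e-05), such as Lum (-1.67), Col6a2 (-1.11) and Dcn (-0.99). Both lists had adjusted p = 0.114 with an estimated correlation. Genes of resting adventitial fibroblasts rose in 2 and fell in 7 of 17 cases (median -0.040, adjusted p = 0.0322, and 0.114 with an estimated correlation), with falls in Cd34 (-1.63) and Dpt (-1.96). With genes below the median level left out this list had a median of 0.019 and adjusted p = 0.71. The epicardial factor Tcf21 (1.18), the pericyte and stromal surface gene Mcam (1.40) and the cytokine Il6 (1.51) rose. Secreted senescence factors, Il6 among them, fell in 7 and rose in 2 of 17 cases (median -0.085, adjusted p = 0.00825 by camera). That list had adjusted p = 0.156 with an estimated correlation and 0.0754 with genes below the median level left out. Other rises were in Clca3a2 (2.37), Rasl11b (2.10), Fstl4 (1.86), Zic2 (1.80) and Npnt (1.68). Further falls were in the chemokine Cxcl15 (-3.44), Anxa8 (-3.12) and Ms4a4d (-2.94). ERK feedback genes, which growth factor signalling induces, rose in 2 and fell in 6 of 12 cases and did not pass as a list (adjusted p = 0.268).

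limma called 5772 genes changed with PDGF-AB at passage 5, 2143 higher and 3629 lower, 278 of them by at least 2-fold. Of 15 lists called by camera, mitosis, DNA replication, interferon response, contractile and cholesterol synthesis genes held with an estimated correlation (adjusted p = 0.0109, adjusted p = 0.00447, adjusted p = 4.0e-04, adjusted p = 5.9e-04 and adjusted p = 0.0279). Over the list memberships 287 were called over all genes and 299 when adjusted over the list alone. The genes of whole chromosomes moved here too, with median changes relative to all placed genes of 0.196 on chromosome 4, 0.183 on chromosome 7 and -0.201 on chromosome 16.

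Treated small colonies at passage 15 were compared with treated small colonies at passage 5. Pip, which encodes a secreted protein of exocrine glands, went from 2.76 ± 0.13 to 10.66 ± 0.062 (adjusted p = 1.9e-18). The first of these levels lay within the range of the Y-linked genes, so no fold is given. Cell division genes also rose, with Ccna2 20.8-fold higher and Mki67 going from 5.60 ± 0.12 to 8.97 ± 0.17. Tcf21 went from 9.56 ± 0.11 to 4.93 ± 0.15, a 24.7-fold fall, and the cytokine Il6 fell 20.2-fold. Pdgfra rose 1.28-fold (adjusted p = 0.00204) and Pdgfrb fell 1.43-fold (adjusted p = 1.3e-06). Cdkn2a stood at 8.11 ± 0.13 and 7.95 ± 0.030 (adjusted p = 0.0974), and passed without treated passage 5 replicate 3 (adjusted p = 0.0295), with arrays centred on their medians (0.0424) and with array weights (0.0414).

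All 19 mitosis genes (median 2.99, adjusted p = 6.1e-23) and all 20 DNA replication genes (median 2.04, adjusted p = 6.0e-19) rose with passage in treated small colonies, including Bub1 (4.28), Kif11 (4.27), Plk1 (4.07), Top2a (4.19) and Chaf1b (3.58). Contractile genes fell in 12 of 16 cases with no rise (median -0.78, adjusted p = 6.4e-10), including Cnn1 (-3.96 ± 0.083) and Myl9 (-1.75). p53 targets fell in 10 of 14 cases (median -0.41, adjusted p = 2.4e-04), such as Btg2 (-2.72) and Fas (-1.93), with adjusted p = 0.0989 under an estimated correlation. Complement and acute phase genes fell in 8 of 10 cases (median -0.69, adjusted p = 2.4e-04), such as Cp (-2.70), C4b (-1.93) and C1s1 (-1.60), with adjusted p = 0.065 under an estimated correlation. Cholesterol synthesis genes fell in 12 of 15 cases (median -0.37, adjusted p = 1.2e-05), with adjusted p = 0.13 under an estimated correlation, as in Msmo1 (-1.35) and Idi1 (-1.32). Immediate early genes fell in 11 of 17 cases (median -0.68, adjusted p = 2.2e-04), among them Fos (-2.63) and Nr4a1 (-2.05), with adjusted p = 0.206 under an estimated correlation.

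Other large rises with passage in treated small colonies were in Glipr1 (4.20 ± 0.070), the glutathione transferase Gsta4 (3.83 ± 0.081) and the cystine transporter Slc7a11 (2.59 ± 0.082). Other large falls were in the superoxide dismutase Sod3 (-4.20), the integrin Itga8 (-4.16), the Wnt inhibitor Nkd2 (-3.22), the matrix protein Tnc (-2.52), Pamr1 (-4.35), Gnai1 (-3.97) and Lmcd1 (-3.81). The lysozyme gene Lyz2, abundant in macrophages, fell by 3.58 ± 0.088, while the 13 macrophage and leukocyte markers had a median of 0.14 and did not pass (adjusted p = 0.951). limma called 9169 genes changed, 4910 higher and 4259 lower at passage 15, and with arrays centred on their medians 3536 were higher and 4950 lower. Of the 9169 genes 1049 changed by at least 2-fold, 492 higher and 557 lower. Of 14 lists called by camera, mitosis, DNA replication and contractile genes held with an estimated correlation (adjusted p = 0.0117, adjusted p = 0.00175 and adjusted p = 0.00226). Over the list memberships 330 were called over all genes and 339 when adjusted over the list alone.

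Treated small and untreated large colonies were compared at each passage as small minus large, a difference in which colony size and PDGF-AB cannot be separated. At passage 5, Gxylt2 (5.25 ± 0.099), Tcf21 (4.85 ± 0.089) and Eng (4.20 ± 0.096) were among the genes far higher in treated small colonies, as was Tbx20, which stood at 8.16 ± 0.020 in them and at the level of the Y-linked genes in large ones. Efemp1 (-7.18 ± 0.066), Gpx3 (-6.65 ± 0.10), Fgf7 (-6.04 ± 0.10) and Thy1 (-5.14 ± 0.074) were among the lowest. Further genes higher in treated small colonies were Srpx2 (3.66), Dpep1 (3.19), Postn (3.12) and Pgm5 (3.07), and further genes lower were Glipr1 (-5.61), Aldh1a3 (-5.58), Tnfsf15 (-5.06) and Limch1 (-5.03). The Wnt agonist Rspo3 (-4.92), the collagen Col14a1 (-4.38), the limb and heart factor Tbx5 (-4.01) and Rgs5 (-3.71) were lower. Mki67 stood at 5.60 ± 0.12 in treated small and 5.41 ± 0.036 in large colonies (adjusted p = 0.113, and 0.0499 without treated small replicate 3). Immediate early genes were higher in 12 of 17 cases (median 0.74, adjusted p = 2.0e-06), such as Fosl1 (1.70), Zfp36 (1.62) and Fos (1.52), and DNA replication genes lower in 11 of 20 cases (median -0.25, adjusted p = 5.0e-04), such as Rrm2 (-1.02) and Rrm1 (-0.98). Both lists had adjusted p = 0.228 with an estimated correlation.

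limma called 7110 genes at passage 5, 2946 higher and 4164 lower in treated small colonies, 726 of them by at least 2-fold. None of the 11 lists called by camera held with an estimated correlation, under which the smallest was adjusted p = 0.228. Over the list memberships 294 were called over all genes and 313 when adjusted over the list alone. Genes of whole chromosomes moved in this comparison, with median changes relative to all placed genes of -0.349 on chromosome 13 and 0.248 on chromosome 12.

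At passage 15, Pip was higher in treated small than in untreated large colonies (10.66 ± 0.062 against 2.70 ± 0.056, adjusted p = 1.7e-18), with the level in large ones again at that of the Y-linked genes. The corneodesmosin gene Cdsn (4.45 ± 0.069), Mpped2 (4.35 ± 0.099) and the adhesion gene Tenm3 (4.23 ± 0.13) were also far higher, and Gxylt2, Slc7a11 and Eng were higher by 4.12, 3.71 and 3.64. Tbx20 stood at 7.23 ± 0.083 in treated small and 3.47 ± 0.031 in large colonies. Gpx3 was 120-fold lower, Fgf7 72.8-fold lower and the semaphorin Sema3c 68.2-fold lower. The Wnt inhibitor Sfrp1 (-5.31), the hormone gene Cck (-5.47), Abi3bp (-6.08), Igf2 (-5.59) and Ms4a4d (-5.39) were also among the lowest. Pdgfra stood at 6.63 ± 0.028 in treated small and 8.84 ± 0.15 in large colonies, 4.63-fold lower, and Mki67 was 1.72-fold higher in treated small colonies.

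Secreted factors linked to senescence were lower in treated small colonies at passage 15 in 12 of 17 cases (median -2.69, adjusted p = 9.4e-09), including Mmp3 (-4.50), Mmp13 (-4.09) and Igfbp5 (-3.55). Resting fibroblast genes were lower in 11 of 17 cases (median -1.17, adjusted p = 6.0e-06), such as Thy1 (-5.14), Cd34 (-3.84) and Mfap5 (-2.37), and contractile genes in 10 of 16 cases (median -0.33, adjusted p = 6.4e-06), such as Actg2 (-4.37) and Cnn1 (-4.22). Complement and acute phase genes were lower in 9 of 10 cases (median -1.43, adjusted p = 4.2e-06), including the C1 inhibitor Serping1 (-4.22). Mitosis genes were higher in 13 of 19 cases (median 0.35, adjusted p = 4.1e-04), such as Cenpe (1.11) and Ccnb2 (1.03), while DNA replication genes were lower in 14 of 20 cases (median -0.31, adjusted p = 0.00224), such as Ccne1 (-1.06) and Ccne2 (-0.86). These last lists had adjusted p = 0.322 and adjusted p = 0.118 with an estimated correlation, and DNA replication had adjusted p = 0.289 with genes below the median level left out. ERK feedback genes were lower in 10 of 12 cases (median -0.52, adjusted p = 2.3e-05, and adjusted p = 0.115 with an estimated correlation), such as Dusp6 (-1.59) and Spry4 (-1.16).

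limma called 10637 genes at passage 15, 5813 higher and 4824 lower in treated small colonies. Of these 925 differed by at least 2-fold, 252 higher and 673 lower. The split of all called genes depended on scaling, with 3428 higher and 5974 lower after centring arrays on their medians and 3674 higher and 4950 lower after cyclic loess. With genes below the median level left out 6829 were called. Of 12 lists called by camera, secreted senescence factors, resting fibroblast, contractile and complement genes held with an estimated correlation (adjusted p = 0.0125, adjusted p = 0.0125, adjusted p = 0.0125 and adjusted p = 0.0148). Over the list memberships 378 were called over all genes and 390 when adjusted over the list alone. The median change of genes on chromosome 12 was 0.334 and on chromosome 17 -0.313 relative to all placed genes.

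**Figure D3:**
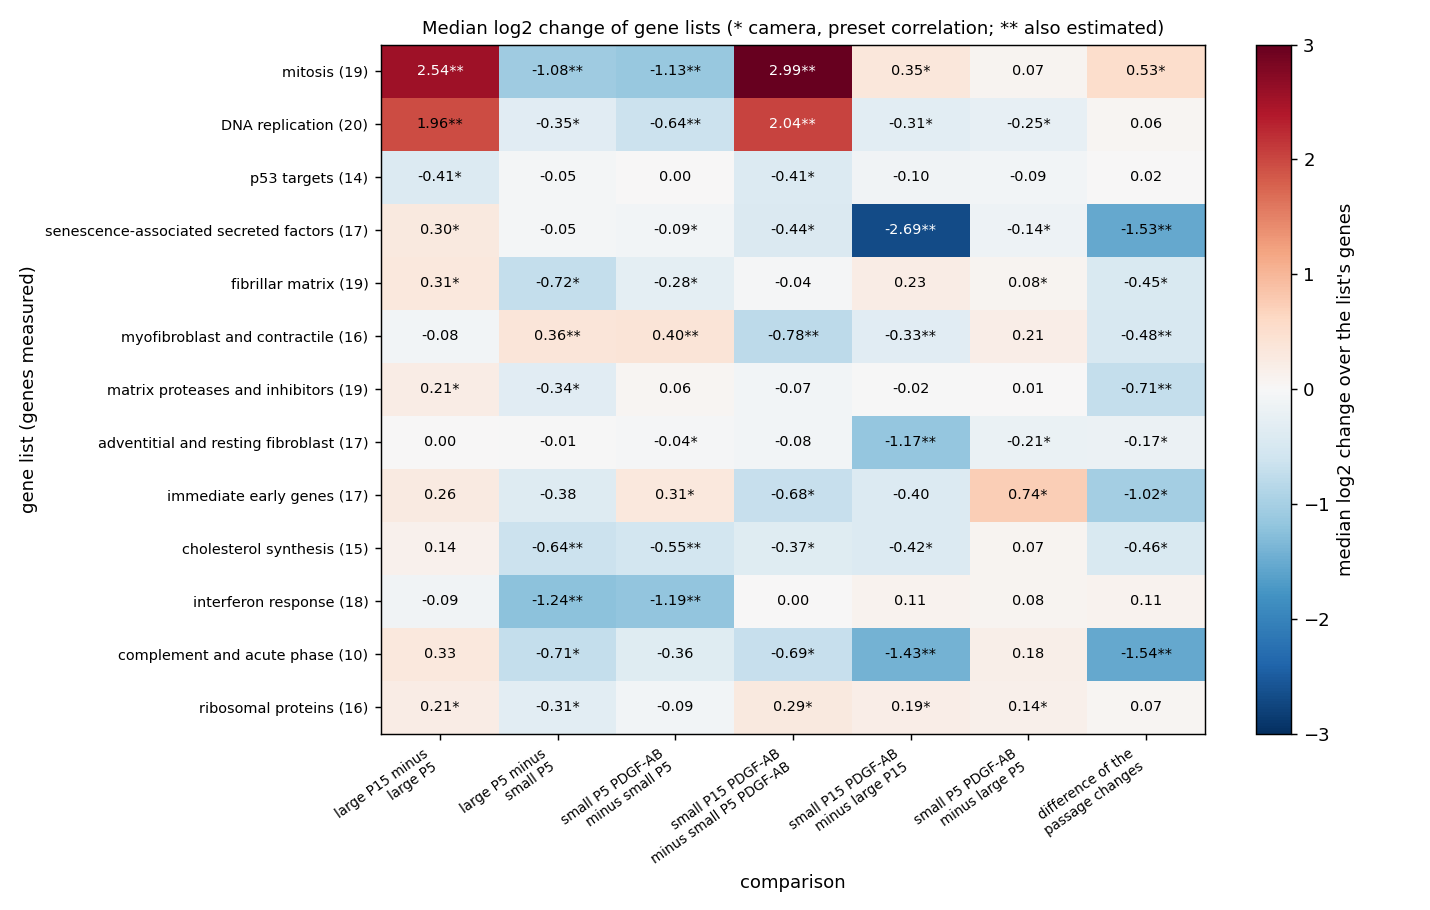
Median log2 change (colour and printed value) of 13 gene lists (vertical axis) in the 7 comparisons (horizontal axis), where 1 star marks a list called by camera at a preset correlation and 2 stars a list also called with an estimated correlation. Mitosis and DNA replication genes had medians above 1.9 with passage in both colony types and below -0.6 with PDGF-AB at passage 5.

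The change with passage in treated small colonies was also compared with that in untreated large colonies, by testing the difference between these changes. Pip was among the largest differences upwards, with a rise in treated small colonies, while it stood at 2.67 ± 0.17 and 2.70 ± 0.056 in large ones, within the range of the Y-linked genes, so that the size of the difference depends on background. Pgm5 differed most downwards (-7.11 ± 0.11), as it rose from 5.01 ± 0.038 to 9.07 ± 0.027 in large colonies and fell from 8.08 ± 0.023 to 5.03 ± 0.20 in treated small ones. Tcf21 (-4.57 ± 0.13), Cnn1 (-4.73 ± 0.12), Mmp3 (-4.69 ± 0.14) and Hgf (-4.23 ± 0.17) also had lower changes in treated small colonies. The rise of Pdgfra in large colonies exceeded that in treated small ones by the same test (-1.91 ± 0.12, adjusted p = 2.7e-09), and Cd34 also differed (-3.52), with a rise in large colonies while it stood at 4.72 ± 0.075 and 4.64 ± 0.10 in treated small ones. Higher changes in treated small colonies were seen in Glipr1 (4.50), Slc7a11 (3.54) and Igfbp2 (3.31). Mki67 differed by 0.59 ± 0.13 (adjusted p = 0.00172).

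Contractile genes had lower passage changes in treated small colonies in 13 of 16 cases (median -0.48, adjusted p = 1.1e-08), secreted senescence factors in 12 of 17 (median -1.53, adjusted p = 1.5e-08), complement genes in 8 of 10 (median -1.54, adjusted p = 1.4e-06) and matrix proteases in 12 of 19 (median -0.71, adjusted p = 1.4e-06). Mesenchymal stromal markers were lower in 8 of 13 cases (median -0.51, adjusted p = 0.00205), such as Nes (-3.07) and Kitl (-1.41). Immediate early genes were lower in 11 of 17 cases (median -1.02, adjusted p = 4.0e-06), for example Fos (-2.63) and Zfp36 (-2.34), and cholesterol synthesis genes in 11 of 15 (median -0.46, adjusted p = 1.6e-07). With an estimated correlation these lists had adjusted p = 0.0971 and adjusted p = 0.0571. Wnt pathway genes had a median of 0.040 but a mean of -0.44, and camera called them lower (adjusted p = 0.0164, and adjusted p = 0.0671 with an estimated correlation). Their median turned to -0.11 after cyclic loess.

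limma called 6865 genes whose passage change differed, 3699 with a higher and 3166 with a lower change in treated small colonies. Of these 844 differed by at least 2-fold, 281 higher and 563 lower. Of all genes called after centring arrays 2387 were higher and 3727 lower, and after cyclic loess 2702 higher and 3515 lower. Of 19 lists called by camera, contractile genes, secreted senescence factors, complement genes, matrix proteases and mesenchymal markers held with an estimated correlation (adjusted p = 0.00628, adjusted p = 0.0193, adjusted p = 0.0193, adjusted p = 0.0232 and adjusted p = 0.0357). Over the list memberships 305 were called over all genes and 325 when adjusted over the list alone.

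Large colonies and PDGF-AB-treated small colonies were each set against untreated small colonies at passage 5, and the changes were compared across genes. Pearson's r across the 19938 genes, which are not independent replicates, was 0.402, where shared controls alone gave 0.501 in simulated noise. The covariance was 0.0589, against 0.00364 in the same 100 simulations. These held no changed genes and only the spread between arrays, so their r is set by the design. A difference of the untreated small culture as a whole would enter both changes and is missing from the simulated covariance. Neither value thus tells likeness from the shared controls. Of 3523 genes called in both, 934 were higher in both, 1788 lower in both and 801 opposite, where independent calls would give 390 higher and 653 lower. Part of that excess may come from the shared controls. Among genes lower in both were Ifit1 (-3.52 and -2.65), Mmp3 (-3.53 and -3.35) and Ogn (-2.71 and -3.21), and Actg2 was higher in both (4.99 and 2.20). Tcf21 moved in opposite directions (-3.67 and 1.18). The passage changes of large and of treated small colonies shared no arrays and had r = 0.499 across genes. Of 4900 genes called in both, 1962 were higher and 2001 lower in both, against 856 and 794 for independent calls, and 937 were opposite. Thus 80.9% moved the same way. In both pairs of comparisons the calls used the same estimate of the spread of each gene. This can raise overlaps in any direction above those of independent calls.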

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

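The comparison of other splits of the arrays and the checks of scaling were chosen before their results were seen, and the tests of sex, chromosome segments, random assignments, likeness across chromosomes, leukocyte markers and correlation between arrays were chosen only after.

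The change with passage differed between treated small and untreated large colonies in 6865 genes by a test of that difference. Differences upwards, as small minus large on the log2 scale, were in Pip (7.87, a size that depends on background because the other 3 groups lay within the range of the Y-linked genes), Glipr1 (4.50), Car6 (3.82), Efemp1 (3.80), Cdo1 (3.63), Slc7a11 (3.54), Igfbp2 (3.31) and Sema3e (3.16). Downwards they were in Pgm5 (-7.11), Cnn1 (-4.73), Dpep1 (-4.70), Mmp3 (-4.69), Tcf21 (-4.57), Npy4r (-4.35), Igf2 (-4.26) and Hgf (-4.23). Among 100 of the 200 possible splits of these arrays, 1, the real one, called as many genes, and the highest of the others called 5201. Arrays of a group correlated at 0.997 or more and arrays of different groups at 0.991 or less. A split that mixes groups therefore adds the differences between them to the spread, which lowers its count whatever the cause. The comparison of splits thus cannot exclude chance as the source of the count. Nor does it exclude chance differences between single cultures, since the arrays of a group may share a culture. The split that turns the passage labels of large colonies alone was not among those drawn. It tests the sum of the passage changes rather than their difference, and it called 8790 genes, which would make 2 of 101 splits.

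In each comparison of a pair of groups 1 of 10 splits, the real one, called as many genes. The real counts and the highest other counts were 7196 and 0 for passage in large colonies, 7216 and 1 for large against small, 5772 and 0 for PDGF-AB, 9169 and 0 for passage in treated small colonies, and 10637 and 0 at passage 15 and 7110 and 0 at passage 5 for treated small against large. With 10 splits a share under 0.05 cannot be reached.

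Xist was high and Y-linked genes low in all 15 arrays of cells labelled male. Xist lay between 8.93 and 9.91 in arrays of large colonies and between 10.29 and 10.88 in arrays of small colonies, and the cause of this difference was not tested. The lowest level of Xist was 8.93, at percentile 85.3 of all genes, where loss of the Y chromosome from male cells would leave Xist silent, so such loss alone is argued against. The highest percentile of any of 5 Y-linked genes was 11.3, where a mixture with male cells would bring the broadly expressed Y-linked genes up in the arrays, so female cells mixed into male cultures are argued against. A label that does not match the sex of the cells remains open and is a candidate explanation. No array of known male cells was among these to show how high the Y-linked probe sets read when their genes are expressed.

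Genes of whole chromosomes moved together between treated small and untreated large colonies, with a largest shift of 0.349 at passage 5, on chromosome 13. Random assignment of genes to chromosomes gave at most 0.105 in 10000 draws. Such draws treat genes as independent replicates, which they are not, so their range may be too narrow here and in the comparisons below. The 4 chromosomes that moved by at least 0.2 at passage 5 were cut into 4 segments of equal gene number each. All 16 segments moved with the whole, and at passage 15 so did 27 of 28 segments of 7 such chromosomes. Both counts go against 1 segment as the cause, though only directions were counted, in chromosomes chosen for their shift. A few genes can hardly move the median of a chromosome, so the counts do not test that explanation. The largest shift at passage 5 was 0.341 after cyclic loess, against scaling that depends on intensity. Cyclic loess takes no account of chromosomes, so it tests no other kind of scaling. The shifts at passage 5 and passage 15 had r = 0.817 across 20 chromosomes (permutation p = 4e-05), Spearman's rho = 0.853 (p = 1e-05, the smallest these permutations can give) and r = 0.736 without chromosomes 13 and 12. Differing gene dosage carried by the cultured lines may account for this and was not measured at the DNA level. Colony size and PDGF-AB cannot be separated in these comparisons, but large and small untreated colonies at passage 5 also differed, by up to 0.320, with 10 of 20 chromosomes beyond all random draws. Treated and untreated small colonies at passage 5 differed by up to 0.201, with 5 beyond all draws, and the passages by up to 0.138 with 3 in large and 0.166 with 2 in treated small colonies, so shifts were not confined to the contrast of small with large colonies.

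Mitosis and interferon response genes fell together with PDGF-AB in small colonies at passage 5. After cyclic loess the higher of their medians was -1.08. Array medians lay between 5.59 and 5.72 before it, so this check could hardly have removed falls of this size. These values go against overall or intensity-dependent scaling as the cause, and other kinds were not tested. The 13 macrophage and leukocyte markers had a median change of 0.00464 with an SD of 0.367. Their median level in untreated small colonies was 4.67, at percentile 28.6 of all genes, with 2 of 13 above the median level, so this median decides nothing. The 2 called markers, Cd14 (-1.24) and Cd68 (-0.23), fell. Per the labels the cells were sorted as SCA1 and PDGFRα positive, which would leave few leukocytes, but their share in the cultures was not measured, so their loss as the source of the interferon part stays open. Arrays of the same group correlated at 0.997 or more, so a response to PDGF-AB and a difference between 1 treated and 1 untreated culture cannot be told apart, because the labels do not say that the arrays came from separate cultures. Genes of whole chromosomes also moved between the treated and untreated small colonies, by up to 0.201 (0.197 after cyclic loess). Random assignment, which treats genes as independent, gave at most 0.0789. These cultures thus differed in a way that gene dosage could bring. Whether PDGF-AB, by selection for example, or a separate history of the cultures brought these shifts was not tested. A response to PDGF-AB and a difference between the cultures may each be the source, and both stay open.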

How the results depend on the processing

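All alternatives in this part were chosen before the data were examined. Counts of called genes stayed within 1.5 times under both scalings, array weights, trend and robust moderation, the compared arrays alone, all probe sets, the mean over probe sets and the replicate block. The minimum of 2-fold by its construction cut them to 751 for passage in large colonies, 783 for large against small, 278 for PDGF-AB, 1049 for passage in treated small colonies, 925 and 726 for treated small against large at passage 15 and passage 5, and 844 for the difference. With genes below the median level left out, fewer genes were tested and 6829 were called at passage 15, 2499 higher and 4330 lower. With the replicate block the counts were 7242, 7198, 5809, 9206, 10703, 7102 and 6946, of which 7026, 7002, 5578, 8979, 10434, 6947 and 6657 were shared with the counts without it. Leaving out 1 array gave 6388 to 7114 for passage in large colonies, 6244 to 7135 for large against small, 4461 to 5687 for PDGF-AB, 8057 to 8676 for passage in treated small colonies, 8982 to 10042 at passage 15, 6297 to 6642 at passage 5 and 5756 to 7229 for the difference. The correlations across genes ranged from 0.389 to 0.427 and from 0.481 to 0.509.

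No named gene changed direction under an alternative where it was called with the main settings or under that alternative. Named genes called in neither were not checked for direction. Of the gene values 1000 kept their side of the threshold under cyclic loess, 32 were lost and 2 gained, and with arrays centred 1011 kept it, 21 were lost and 2 gained. With 1 array left out 6967 of the values kept it, 141 were lost and 8 gained. No scaling moved the median of all genes by over 0.1. Of the list results 189 kept their side with an estimated correlation and 70 lost it. With cyclic loess 12 were lost and 7 gained, with genes below the median level left out 28 were lost and 10 gained, and with 1 array left out 17 of the list values were lost and 9 gained. fry gave the opposite direction to camera in 23 list results, of which camera called none. In 14 neither test passed, and in 9 fry alone passed, with median changes of 0.14 for macrophage markers, 0.066 for cardiomyocyte markers and 0.10 for pericyte markers with passage in treated small colonies; 0.23 for fibrillar matrix, -0.13 for antioxidant genes, -0.23 for the unfolded protein response and 0.17 for bone and cartilage markers at passage 15; and 0.027 at passage 5 and 0.11 in the difference for pericyte markers. The cause was not tested. Genes near the background of the array limit what can be seen. Among simulated changes of 0.25, 20% were called, against 92% of those of 0.5. The simulation changed few genes, drawn at random, so these shares measure neither the effect of background nor the sensitivity of the real comparisons.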

Other observations

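No test in this part was chosen after its result was seen, and the values are given with no explanation.

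BMP response genes were higher in large than in small untreated colonies at passage 5 in 7 of 12 cases (median 0.43, adjusted p = 0.0117, and adjusted p = 0.209 with an estimated correlation), including Id2 (1.57), Smad7 (1.01) and Smad6 (0.92), and lower in treated small than in large colonies at passage 15 in 9 cases (median -0.74, adjusted p = 5.8e-04, and adjusted p = 0.115 with an estimated correlation). Among Wnt pathway genes the inhibitor Sfrp1 (2.89) and the agonist Rspo3 (3.35) were higher and the ligand Wnt5a lower (-2.44) in large untreated colonies, and at passage 15 the list had a median of -0.0001 and a mean of -0.79 (adjusted p = 0.0466), with adjusted p = 0.0526 without large passage 15 replicate 3, 0.0527 with the replicate block and 0.115 with an estimated correlation. TGF-beta response genes were lower in treated small colonies at passage 15 in 8 of 13 cases (adjusted p = 0.00714), with adjusted p = 0.0516 after cyclic loess, 0.222 with genes below the median level left out and 0.376 with an estimated correlation. Of the PDGF ligand genes, Pdgfc was lower (-1.57) and Pdgfd higher (1.65) in large untreated colonies, and the list of PDGF ligands and receptors did not pass (adjusted p = 0.873). Basement membrane genes were lower in 6 and higher in 3 of 14 cases in large untreated colonies (adjusted p = 0.0239, and adjusted p = 0.549 with an estimated correlation), with Lama4 at -3.81 and Nid2 at -1.98, and had adjusted p = 0.103 with genes below the median level left out.

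Ribosomal protein genes rose with passage in 10 of 16 cases (median 0.21, adjusted p = 0.00232, 0.249 with an estimated correlation) in large colonies and in 11 of 16 cases (median 0.29, adjusted p = 0.00268, 0.187 with an estimated correlation) in treated small ones. They were lower in large than in small untreated colonies in 13 of 16 cases (median -0.31, adjusted p = 5.1e-05, 0.0868 with an estimated correlation), and higher in treated small than in large colonies in 8 of 16 cases (median 0.14, adjusted p = 0.00869, 0.317 with an estimated correlation) at passage 5 and 11 of 16 cases (median 0.19, adjusted p = 0.00669, 0.241 with an estimated correlation) at passage 15. Glycolysis genes were lower in large than in small untreated colonies in 9 of 16 cases (median -0.35, adjusted p = 5.8e-04, 0.0995 with an estimated correlation), with Pdk1 at -1.76 and Ldha at -0.68. They fell with PDGF-AB in 7 of 16 cases (median -0.15, adjusted p = 0.00356, 0.143 with an estimated correlation) and with passage in treated small colonies in 8 of 16 cases (median -0.19, adjusted p = 0.0373, 0.246 with an estimated correlation), and their passage change was lower in treated small colonies in 9 of 16 cases (median -0.24, adjusted p = 0.0133, 0.195 with an estimated correlation). Of these calls, that with passage had adjusted p = 0.0646 after cyclic loess and 0.112 with genes below the median level left out, and that of the difference 0.0616 with such genes left out. Between treated small and large colonies at passage 5, camera called glycolysis only after cyclic loess (adjusted p = 0.0373), without large passage 5 replicate 1 (0.0396) and without treated passage 5 replicate 1 (0.0401). Oxidative phosphorylation genes rose with passage in large colonies in 10 of 25 cases (median 0.098, adjusted p = 0.0225, 0.299 with an estimated correlation), fell with PDGF-AB in 13 of 25 cases (median -0.19, adjusted p = 0.00568, 0.178 with an estimated correlation) and were lower in treated small than in large colonies at passage 5 in 12 of 25 cases (median -0.16, adjusted p = 0.0244, 0.335 with an estimated correlation). After cyclic loess these had adjusted p = 0.0569, 0.0689 and 0.0661, and with genes below the median level left out 0.152, 0.154 and 0.112. With passage in treated small colonies camera called them only after cyclic loess (0.0171) and with such genes left out (0.0424).

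Antioxidant targets of NRF2 were lower in treated small than in large colonies at passage 5 in 8 of 11 cases (median -0.58, adjusted p = 0.00272, 0.228 with an estimated correlation), and their passage change was higher in treated small colonies in 5 of 11 cases (median 0.15, adjusted p = 0.00549, 0.143 with an estimated correlation), with a mean of 0.77. They fell with passage in large colonies in 6 of 11 cases (median -0.34, adjusted p = 0.0255, 0.299 with an estimated correlation), with adjusted p = 0.0543 without large passage 15 replicate 3. Between large and small untreated colonies camera called them only after cyclic loess (adjusted p = 0.0395), without large replicate 3 (0.0488) and without small replicate 1 (0.0484) or 2 (0.0438). Cholesterol synthesis genes were also lower in treated small than in large colonies at passage 15 in 11 of 15 cases (median -0.42, adjusted p = 1.6e-05, 0.115 with an estimated correlation), and at passage 5 camera called them only after cyclic loess, as higher (median 0.12, adjusted p = 0.0373). Genes of the unfolded protein response fell with PDGF-AB in 9 of 15 cases (median -0.20, adjusted p = 0.00659, 0.156 with an estimated correlation), with adjusted p = 0.0523 after cyclic loess. With genes below the median level left out, the passage calls in large colonies were lost for ribosomal proteins (adjusted p = 0.0546) and antioxidant genes (0.0709), as was the call of the unfolded protein response with PDGF-AB (0.133). CDK inhibitors passed as a list in none of the 7 comparisons (smallest adjusted p = 0.336), and neither did pluripotency and self-renewal factors (smallest adjusted p = 0.139).

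Markers of other cell types were mostly below the median level, with 2 of 12 endothelial, 2 of 13 macrophage and leukocyte and 2 of 13 cardiomyocyte genes above it. The passage change of endothelial markers was higher in treated small than in large colonies in 7 of 12 cases (median 0.32, adjusted p = 0.00767, 0.214 with an estimated correlation), with adjusted p = 0.0608 with genes below the median level left out, where the median of the 2 remaining genes was 0.80. Endothelial markers rose with passage in treated small colonies in 6 of 12 cases (median 0.26, adjusted p = 0.0454), with adjusted p = 0.0952 after cyclic loess, 0.112 with genes below the median level left out (median 0.78 of 2 genes), 0.105 without treated passage 5 replicate 1, 0.0590 without treated passage 15 replicate 2 and 0.333 with an estimated correlation. Cardiomyocyte markers rose with PDGF-AB in 2 of 13 cases (median 0.14, adjusted p = 0.00825), among them Tnnt2 (0.78), with adjusted p = 0.0900 after cyclic loess and 0.114 with an estimated correlation. Between treated small and large colonies at passage 15 camera called them only with genes below the median level left out (median 0.99 of 2 genes, adjusted p = 0.0479). Adipocyte markers had a lower passage change in treated small colonies in 4 of 11 cases (adjusted p = 0.0403), with adjusted p = 0.0846 without large passage 5 replicate 1, 0.0630 without treated passage 15 replicate 3 and 0.102 with an estimated correlation. Bone and cartilage, pericyte, epicardial and mesothelial, Schwann cell, macrophage and leukocyte and Y-linked lists passed in none of the 7 comparisons, with smallest adjusted p = 0.0645, 0.159, 0.0839, 0.232, 0.629 and 0.714. Some of these were called by camera under an alternative. With genes below the median level left out, the 2 remaining macrophage and leukocyte markers were lower in treated small than in large colonies at passage 15 (median -2.12, adjusted p = 0.0479) and in the passage change (-2.67, 0.0056). Epicardial and mesothelial markers passed after cyclic loess with PDGF-AB (-0.061, adjusted p = 0.0483) and without large passage 5 replicate 1 between treated small and large colonies at passage 5 (-0.14, 0.0441), and bone and cartilage markers with passage in treated small colonies without treated passage 5 replicate 3 (0.22, adjusted p = 0.0446).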
